A study of Rattus norvegicus with 24 samples.

How the data were processed

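Punches of lateral striatum and of substantia nigra from adult male Sprague Dawley rats were hybridised to Affymetrix arrays read at the level of exon probe sets, 12 arrays per tissue. In each tissue 3 arrays came from each of 4 groups: lesioned rats given levodopa that became dyskinetic, lesioned rats given levodopa that did not, lesioned rats given no levodopa, and rats without the toxin given levodopa. Dyskinesia was rated by the authors, and a lesion counted as successful per the labels when striatal dopamine loss was over 90%. Of the 14 animals 10 gave both tissues and 4 gave 1 tissue. The side sampled, the levodopa dose and the time between the last dose and death were not given in the labels.

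The deposited values are log2 values that the authors made with the robust multi-array average in oligo 1.34 under R 3.2.3. Values ran from 2.62 to 14.5, none of the 24 columns had a missing value, and the mean of the array medians was 7.94 in striatum and 8.25 in nigra, so levels were compared within a tissue, except to pick genes enriched in either tissue and to estimate a share of striatal tissue in the nigral punches. Of 213067 probe sets 172924 name 1 gene, 1661 several and 38482 none in the annotation deposited with the array, which dates from 2010. The 16633 symbols were brought up to date with the gene table of rat assembly GRCr8: 12878 were current, 3700 were updated by a synonym and 55 were kept as given. A gene's value is the mean over the probe sets that name it alone (median 8, quartiles 4 and 14), which gave 16582 genes. Probe sets naming several genes or none were left out of the comparisons and tested apart. The lowest 25% of genes by mean over the tissue were left out, and 12436 were tested in each tissue.

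Differences were fitted with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), with lmFit and eBayes over the 12 arrays of a tissue and 1 mean per group, and p was adjusted by the method of Benjamini and Hochberg at a threshold of 0.05. Comparisons were dyskinetic against non-dyskinetic, each of these against lesioned vehicle, the mean of both levodopa-treated lesioned groups against intact, and lesioned vehicle against intact. Whether the first of these differed between tissues was tested over all 24 arrays, with the animal as a random block (correlation 0.152). The standard error given is the one from the moderated variance, which takes the spread of a gene as equal in all groups of the fit. Lists of 284 genes in 22 groups, written from general knowledge before the data were examined, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison, in 242 tests. Members were also counted past the threshold over all genes and with p adjusted over the list alone. The lists were immediate early genes, neuropeptides and secreted factors, ERK feedback genes, direct-pathway, indirect-pathway and pan-projection neuron markers, dopamine and cAMP signalling, dopamine neuron markers, glutamate receptors, GABA genes, serotonin receptors, markers of astrocytes, microglia, oligodendrocytes, endothelium, choroid plexus, cortical neurons, striatal interneurons and midbrain glutamatergic neurons, interferon genes, stress genes and oxidative phosphorylation. A gene may stand in several lists: Th counts as a marker of dopamine neurons and of interneurons, and Pdyn, Tac1 and Penk as neuropeptides and pathway markers. Of the listed genes 25 had no probe set of their own and were not analysed here.

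Genes are named by a rule fixed before the data were examined. It names, per comparison, the 12 largest rises and 12 largest falls past the threshold whose compared arrays do not overlap, up to 4 members of a list past the threshold, and, where fewer than 10 genes pass, the 5 highest and 5 lowest statistics. Within a tissue, a lack of overlap stated for the largest rises and falls follows from this rule and is no separate result. Fosb, Pdyn, Nr4a2, Trh, Penk, Drd1, Drd2 and Th are named always, with Slc6a3, Slc18a2 and Ddc in the nigra as a check on the lesion. Symbols of predicted genes were passed over, 1 in the nigra of levodopa-treated lesioned against intact rats and 3 in that of vehicle against intact rats. All of the largest rises and falls are named, and for space only some of the list members, chosen with their values in view. Exceptions, named after their values were seen, are the genes called in both tissues and those high in single nigral vehicle arrays.

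Recovery was tested on simulated data with 200 changed genes per comparison. Between 71.6% and 86.6% of changes of 0.5 log2 were recovered within a tissue and 58.2% in the tissue difference, and at a change of 1 at least 95.5% in each. Unchanged genes made up 2.08% to 8.87% of the calls, against the 5% aimed at, with 7.46% for dyskinetic against non-dyskinetic striatum, 8.87% for the same in nigra and 8.74% for the tissue difference. A list of 12 genes shifted by 0.5 was called in 10 of 10 runs with both correlations, and 0 of 190 unchanged lists by camera. The simulated genes varied independently of one another. These runs therefore do not test the preset correlation where genes of a list vary together. Each simulated gene also had the same spread in every group, so the share of false calls does not cover groups of unequal spread. Arrays correlated within a tissue at r of 0.983 to 0.997. The animals behind replicate numbers differed between groups, so arrays were not paired.

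Alternatives fixed before the data were examined were trended and robust variances, no filter or a filter at 50%, the median over probe sets, a further quantile normalization, only the compared groups in the fit, all 24 arrays with an animal block, array weights, the replicate number as a block, each compared array left out in turn, and for the tissue difference no animal block. Leaving out vehicle arrays 1 and 3 of the nigra together was added after seeing the data, as was a list of 23 leptomeningeal markers, of which 14 were tested. For each comparison other splits of the compared arrays were counted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.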

Results

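Transcript levels were measured on exon-level microarrays in tissue punches from 14 adult male rats, 10 of which gave both tissues studied, the striatum and the substantia nigra. The 24 arrays fell into 4 groups of 3 in each tissue. Dyskinetic and non-dyskinetic rats had both received 6-hydroxydopamine, a toxin that destroys dopamine neurons, and then daily levodopa, the dopamine precursor. Only the first had developed the abnormal involuntary movements called levodopa-induced dyskinesia. Vehicle-treated rats had the same lesion and no levodopa, and intact rats had saline in place of the toxin and were given levodopa. No group was intact and free of levodopa. All 16582 genes are given as the mean log2 value of their probe sets, a log2 difference of 1 is a doubling, and 12436 genes per tissue were tested. The value after ± is the standard error of the fitted difference, or the SD of 3 arrays where a group mean is given; the number of arrays limits the precision of both.

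**Figure D1:**
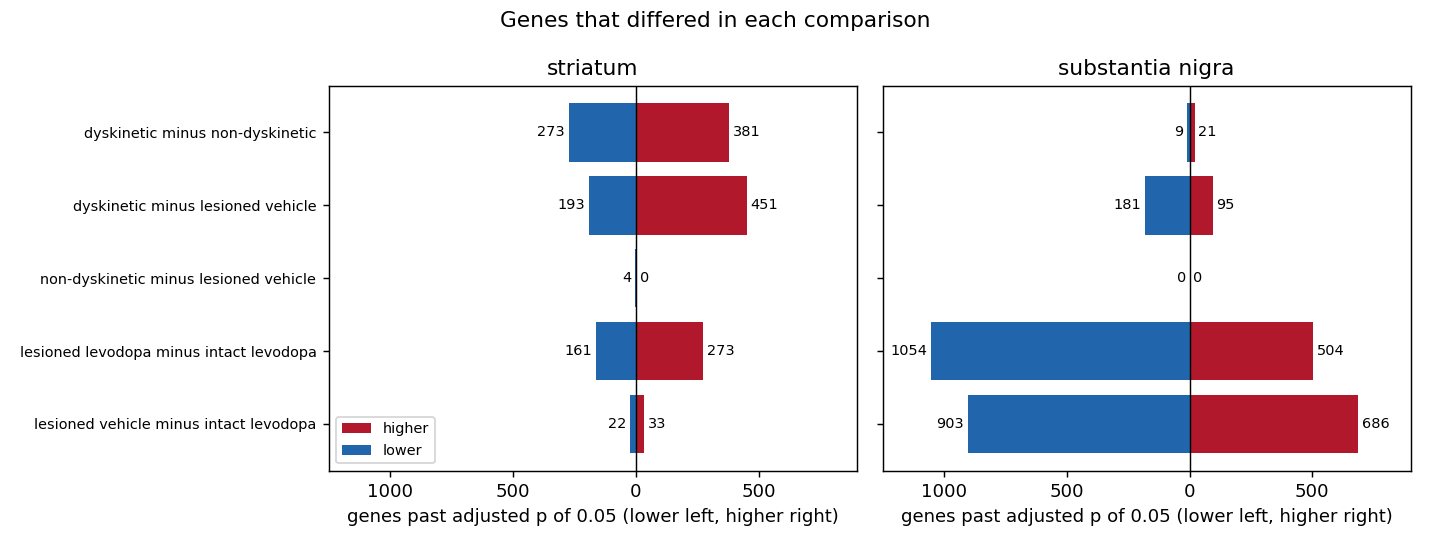
Bars give the number of genes past an adjusted p of 0.05 in each of 5 comparisons per tissue, genes higher in the first-named group to the right in red and genes lower to the left in blue. In the striatum 654 genes differed between dyskinetic and non-dyskinetic rats, and in the nigra 1589 differed between lesioned vehicle and intact rats.

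The striatum of dyskinetic rats was set against that of non-dyskinetic rats. Both groups had received the toxin and levodopa and differed in the movements; the size of the lesion in each animal was not in the labels and is not known to be equal. The largest rises in the dyskinetic rats held Nr4a2 and Fosb, immediate early genes, which neurons switch on within minutes of activity. They also held the neuropeptide genes Trh and Nmu. Levels of the immediate early genes depend on the time between the last dose and death, which was not in the labels. Nr4a2, a nuclear receptor and immediate early gene that dopamine neurons also need, stood at 10.56 ± 0.76 (mean ± SD, n = 3) against 7.11 ± 0.75 in non-dyskinetic rats, a rise of 3.45 ± 0.33. Trh, the precursor of thyrotropin-releasing hormone, stood at 10.94 ± 1.04 against 7.86 ± 0.01, a rise of 3.09 ± 0.32. Pdyn, the dynorphin precursor of striatal neurons that project directly to the nigra, rose by 1.66 ± 0.17, and Fosb, a subunit of the transcription factor AP-1, by 1.96 ± 0.24. Th, the rate-limiting enzyme of dopamine synthesis, stood at 7.33 ± 0.47 against 6.18 ± 0.15 and rose by 1.15 ± 0.17. The adjusted p of these 5 genes ran from 3.1e-05 to 9.2e-04, and all 3 dyskinetic arrays lay above all 3 non-dyskinetic arrays for each. The spread was not equal between groups for such genes. The SD of the mean of the immediate early genes was 0.22 in dyskinetic, 0.49 in non-dyskinetic, 0.09 in vehicle and 0.07 in intact striatum. Standard errors and adjusted p pooled over the 4 groups can thus be too small here.

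Other large rises in the dyskinetic striatum were those of Timp1, an inhibitor of matrix metalloproteinases (2.80 ± 0.41), Cdkn1a, the cell-cycle inhibitor p21 (2.78 ± 0.21), and the neuropeptide gene Nmu (2.41 ± 0.28). The somatostatin receptor Sstr2 rose by 2.23 ± 0.16, the activin subunit Inhba by 2.22 ± 0.19, the vitamin D receptor Vdr by 2.11 ± 0.17 and Gpr3, a receptor that activates adenylyl cyclase without a ligand, by 2.10 ± 0.21. Dusp5 and Dusp2, phosphatases that switch off MAP kinases, rose by 1.87 ± 0.26 and 1.84 ± 0.15. Falls were smaller. The orphan receptor Gpr139 (-1.44 ± 0.29), the vesicle protein Syt2 (-1.25 ± 0.12), the cadherin Cdh7 (-0.87 ± 0.18), the death ligand Tnfsf10 (-0.80 ± 0.14) and the serotonin receptor Htr1f (-0.80 ± 0.10) were lower in dyskinetic rats. So were Sytl5 (-0.72 ± 0.11), Lrch2 (-0.72 ± 0.17), the ectonucleotidase Entpd3 (-0.68 ± 0.10), Cc2d2a (-0.64 ± 0.13), the semaphorin receptor Plxnd1 (-0.60 ± 0.080), the kinase Matk (-0.60 ± 0.087) and the adhesion molecule L1cam (-0.59 ± 0.084). Adjusted p ran from 4.1e-06 to 0.019, and none of these genes had overlapping groups, as the naming rule required. Drd1 (0.13, adjusted p = 0.42), Drd2 (-0.10, adjusted p = 0.43) and Penk (0.078, adjusted p = 0.60) did not pass.

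By gene group, 12 of the 17 immediate early genes rose in the dyskinetic striatum, none fell and 5 did not pass over all genes. Adjusted over the list alone all 17 rose. Nr4a3 (1.30 ± 0.27), Arc (1.23 ± 0.24) and Npas4 (1.21 ± 0.22) were among them, and the list median was 1.07. The list passed camera (adjusted p = 3.6e-22) but not with an estimated correlation (adjusted p = 0.080 with an estimated correlation). Of 12 neuropeptides and secreted factors 8 rose and none fell (9 adjusted over the list alone), among them the pentraxin Nptx2 (1.66 ± 0.17) and the peptide Cck (1.60 ± 0.17). This list passed with both correlations (adjusted p = 3.8e-18, and adjusted p = 0.024 with an estimated correlation). Of 14 ERK feedback genes 5 rose and none fell (6 up and 1 down adjusted over the list alone), with Ier3 (1.60 ± 0.18), Phlda1 (1.23 ± 0.16) and Dusp4 (adjusted p = 6.7e-05) beside Dusp5. Their camera call (adjusted p = 2.8e-04) was lost with the estimated correlation (adjusted p = 0.24 with an estimated correlation). The stress genes Hspb1 (0.76 ± 0.21), Dnajb1 (0.70 ± 0.15) and Ddit3 (0.64 ± 0.11) rose of 10 in their list (adjusted over the list alone also 3). For the list, camera gave adjusted p = 2.8e-04, and adjusted p = 0.080 with an estimated correlation.

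Among the receptors and neuron markers of the striatum, Pdyn was the only one of 9 direct-pathway markers to pass over all genes (2 up and 1 down adjusted over the list alone), and none of 5 indirect-pathway or 12 pan-projection neuron markers passed over all genes or adjusted over the list alone. Htr1b (0.53 ± 0.080) rose and Htr4 (-0.47 ± 0.089) fell among 9 serotonin receptors. The dopamine receptor Drd3 (0.43 ± 0.11) and the transcription factor Crem (0.45 ± 0.094) rose among 23 dopamine and cAMP signalling genes, whose median was -0.083 and mean -0.0073. Gad1 (0.39 ± 0.088) and Slc32a1 (0.48 ± 0.10), which make GABA and load it into vesicles, rose among 14 GABA genes, a list whose median was -0.069 and mean -0.015 although camera put it up (adjusted p = 0.97). The serotonin receptors likewise had a median of -0.030 and a camera direction of up (adjusted p = 0.97). Camera sets a list against the other genes rather than against no change, and the median over all genes was -0.031 in this comparison. Th was the only member to pass of 11 dopamine neuron markers (camera adjusted p = 0.091).

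In all, 654 of 12436 genes passed in the striatum of dyskinetic against non-dyskinetic rats, 381 higher and 273 lower, and 2655 had an unadjusted p under 0.05 where 621.8 would by chance. Of the 57 that differed by at least a doubling, 55 were higher in dyskinetic rats. The groups did not overlap in 2929 genes (23.6%), where chance gives 10% for 3 against 3, and in 650 of the 654. The count was 293 without dyskinetic array 2, 387 without non-dyskinetic array 2, 392 without non-dyskinetic array 3, and 352 with the median over probe sets and 388 with only these 6 arrays in the fit. Without dyskinetic array 2 the adjusted p was 0.057 for Nr4a3, 0.16 for Drd3 and 0.085 for Gad1. Crem (0.053), Hspb1 (0.12) and Lrch2 (0.093) were lost without non-dyskinetic array 2 and Dnajb1 (0.057) without array 3 of that group, and Gpr139 with trended variances (0.064). Over 15 alternative settings Hspb1 lost its call in 10, Drd3 in 6, Dnajb1 and Gad1 in 5 each and Lrch2 in 4.

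**Figure D2:**
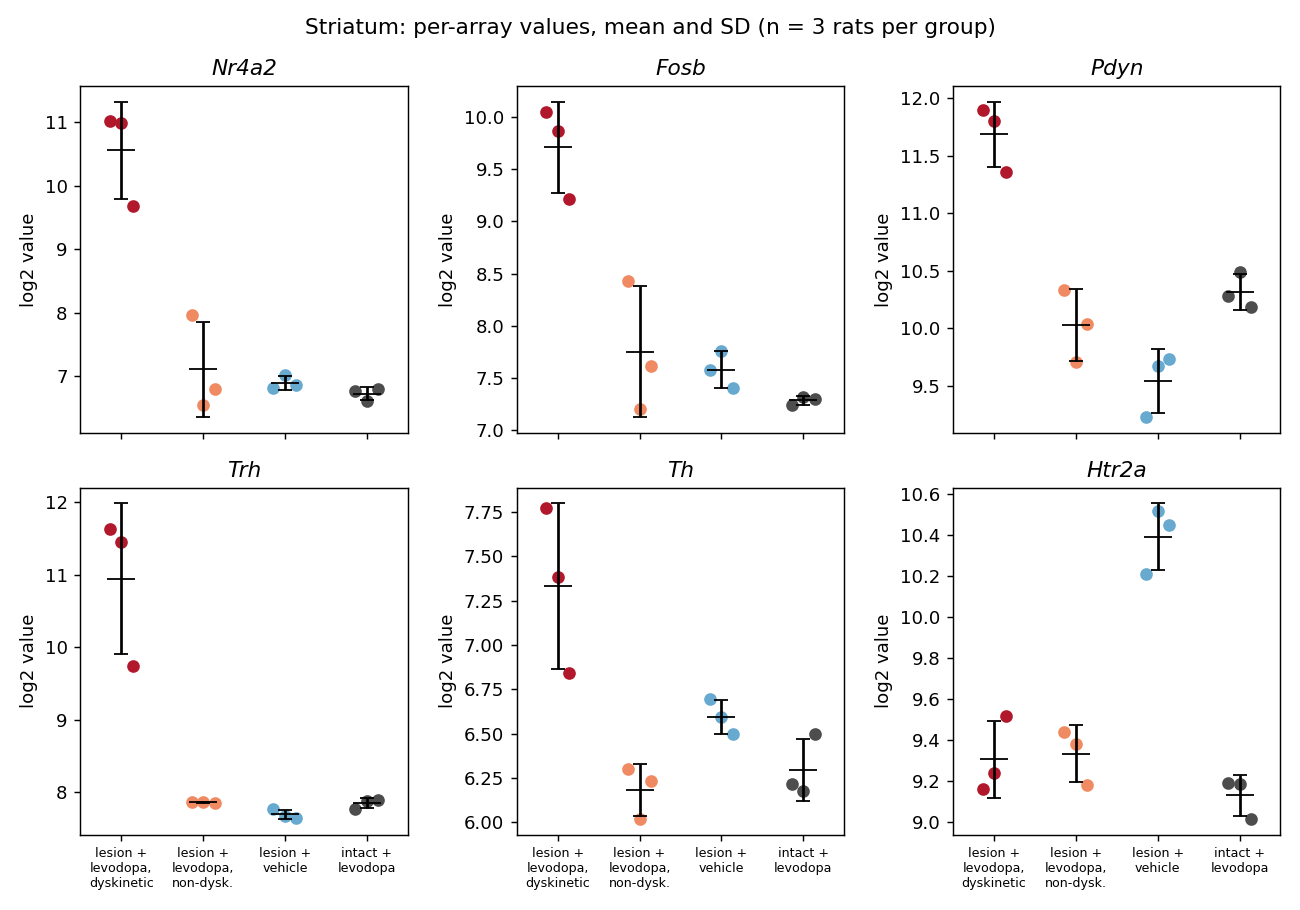
Each point is the log2 value of a gene on a striatal array, with the mean and SD of the 3 arrays per group, for Nr4a2, Fosb, Pdyn, Trh, Th and Htr2a. The dyskinetic arrays lie above the other groups for Nr4a2, Fosb, Pdyn and Trh, and the lesioned vehicle arrays lie above the rest for Htr2a.

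Dyskinetic rats were also set against lesioned rats given vehicle in place of levodopa, a comparison of drug plus movements against lesion alone. In the striatum Nr4a2 rose by 3.66 ± 0.33, Trh by 3.25 ± 0.32, Pdyn by 2.14 ± 0.17 and Fosb by 2.13 ± 0.24. Egr2, an immediate early transcription factor, rose by 2.34 ± 0.36, Cdkn1a by 2.82 ± 0.21, Timp1 by 2.31 ± 0.41, Gpr3 by 2.31 ± 0.21 and Vdr by 2.21 ± 0.17. Dusp5 (2.23 ± 0.26), Sstr2 (2.21 ± 0.16) and Dusp2 (2.03 ± 0.15) completed the 12 largest rises. Htr2a, the serotonin receptor of the type 2A class, stood at 9.30 ± 0.19 (SD, n = 3) against 10.39 ± 0.16 in vehicle rats and fell (-1.09 ± 0.11). Gpr139 (-1.63 ± 0.29), Tnfsf10 (-1.04 ± 0.14), the ceramidase Acer2 (-0.95 ± 0.15), the Wnt receptor Fzd8 (-0.86 ± 0.13) and the activin antagonist Fst (-0.85 ± 0.17) fell as well. So did the guidance cue Sema3a (-0.84 ± 0.15), Syt2 (-0.82 ± 0.12), the homeobox gene Meox2 (-0.79 ± 0.17), Ankrd34b (-0.76 ± 0.11), the protocadherin Pcdh20 (-0.74 ± 0.12) and Htr1f (-0.70 ± 0.10). Adjusted p ran from 3.1e-06 to 0.011, and the 3 arrays of each group did not overlap for any of them.

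Of 17 immediate early genes 16 rose over all genes and adjusted over the list alone, none fell and 1 did not pass (median 1.19). As a list they had a camera adjusted p of 7.2e-27 (adjusted p = 0.058 with an estimated correlation). Of 12 neuropeptides and secreted factors 8 rose (9 adjusted over the list alone), with Inhba (1.90 ± 0.19), Nptx2 (1.65 ± 0.17) and Cck (1.45 ± 0.17) among them. The list passed with both correlations (adjusted p = 2.5e-16, and adjusted p = 0.034 with an estimated correlation). Of 14 ERK feedback genes 5 rose (9 up and 1 down adjusted over the list alone). Over the list camera gave adjusted p = 5.3e-09, and adjusted p = 0.058 with an estimated correlation. Among 9 direct-pathway markers Pdyn, the substance P precursor Tac1 (0.66 ± 0.11), Drd1 (0.35 ± 0.086) and Slc35d3 (0.28 ± 0.069) rose (5 up and 2 down adjusted over the list alone). That list's camera call (adjusted p = 0.030) was lost with the estimated correlation (adjusted p = 0.13 with an estimated correlation). Th rose by 0.74 ± 0.17. The choline acetyltransferase Chat (-0.52 ± 0.11) and the myelin genes Cldn11 (-0.33 ± 0.086) and Mog (-0.27 ± 0.073) fell. The 12 oligodendrocyte markers had a camera adjusted p of 0.030 (adjusted p = 0.32 with an estimated correlation). Dopamine receptor Drd2 (-0.10, adjusted p = 0.50) and Penk (-0.063, adjusted p = 0.74) did not pass.

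In this comparison with vehicle rats 644 genes passed, 451 higher and 193 lower, with 2237 at an unadjusted p under 0.05, and groups did not overlap in 23.0% of genes (10% by chance). The count was 382 without dyskinetic array 1, 384 without dyskinetic array 2, 419 without vehicle array 2, 381 with the median over probe sets and 1152 with array weights. Drd1 lost its call without any of 5 arrays (highest adjusted p 0.11, without vehicle array 1), Th without any of 4 (0.076, without dyskinetic array 2), Slc35d3 without any of 6 (0.099, without dyskinetic array 2), Cldn11 without any of 5 (0.14, without vehicle array 2) and Mog without any of 6 (0.15, without dyskinetic array 2). Meox2 was at 0.062 without dyskinetic array 1.

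Dyskinetic arrays were higher than both other lesioned groups in 305 genes and lower than both in 99, where 13.8 and 4.24 would be called in both comparisons if they were independent. Independence leaves out that both comparisons use the same dyskinetic arrays. Simulated data without any effect gave an overlap of 0 in 50 simulations, but data without an effect call almost no gene, so neither value bounds the overlap the shared arrays bring. The fold changes of the pair of comparisons correlated across genes at r = 0.829 with a covariance of 0.0357, against r = 0.498 and a covariance of 0.00570 in the simulations; genes are not independent replicates. The 3 dyskinetic arrays cannot be split into separate sets, so part of the excess may come from the shared arrays.

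Levodopa without dyskinesia was compared with the lesion alone through the non-dyskinetic and vehicle rats. A single large difference stood out in the striatum: Htr2a was at 9.33 ± 0.14 (SD, n = 3) in non-dyskinetic and 10.39 ± 0.16 in vehicle rats and fell (-1.06 ± 0.11, adjusted p = 9.4e-04). The metalloproteinase Mmp9 (-0.66 ± 0.093), the keratin Krt17 (-0.61 ± 0.093) and Vxn (-0.56 ± 0.084) also fell, at adjusted p of 0.025 to 0.028, with no overlap between groups for any of the 4. Nr4a2 (0.21, adjusted p = 0.91), Fosb (0.17, adjusted p = 0.90), Trh (0.16, adjusted p = 0.93), Pdyn (0.48, adjusted p = 0.63), Th (-0.41, adjusted p = 0.73), Penk (-0.14, adjusted p = 0.75), Drd1 (0.23, adjusted p = 0.69) and Drd2 (adjusted p = 1.0) did not pass. Nor did the genes with the next most extreme statistics, the highest being Fam184a (0.52, adjusted p = 0.062), Maf (0.62), Zdhhc13 (0.38), Efnb3 (0.44) and Shh (0.45) and the lowest beside those called Prokr2 (-0.52, adjusted p = 0.060).

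No immediate early gene passed in this comparison over all genes or adjusted over the list alone (median 0.21). With camera the list was at adjusted p = 0.041, and at adjusted p = 0.61 with an estimated correlation. No direct-pathway marker passed over all genes, and 4 of 9 rose adjusted over the list alone, Pdyn, Tac1 (0.33), Drd1 and Slc35d3 (0.19). Dusp4 (0.44), Dusp6 (0.39) and Spred1 (0.24) rose adjusted over the ERK feedback list alone (camera adjusted p = 0.0049, adjusted p = 0.37 with an estimated correlation). With limma 4 genes passed, 0 higher and 4 lower, 833 had an unadjusted p under 0.05, and groups did not overlap in 10.0% of genes, with 10% given by chance. Leaving out single arrays gave 1 to 12 genes, and Mmp9, Krt17 and Vxn each lost the call without any of 4 or 5 of the 6 arrays (highest adjusted p 0.15 without non-dyskinetic array 3, 0.19 without vehicle array 2 and 0.19 without vehicle array 2), while Htr2a kept it each time.

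The mean of both levodopa-treated lesioned groups was set against intact rats on levodopa, so that a difference in either lesioned group alone can bring a call. In the striatum Inhba rose by 1.88 ± 0.17, the peptide precursor Nts (neurotensin) by 1.80 ± 0.19 from 6.54 ± 0.40 in intact rats (SD, n = 3), Sstr2 by 1.44 ± 0.14, Nptx2 by 1.38 ± 0.15 and Ptgs2, the inducible cyclooxygenase, by 1.35 ± 0.16. The kinase Plk3 (1.30 ± 0.14), the GTPase Rem2 (1.15 ± 0.13), the prohormone convertase Pcsk1 (1.09 ± 0.086), Phlda1 (1.08 ± 0.14), Tnnt1 (1.05 ± 0.10), Mmp9 (1.00 ± 0.080) and the neurokinin B precursor Tac3 (0.99 ± 0.10) rose as well. Falls included Tmem132e (-0.94 ± 0.12), the potassium channels Kcng1 (-0.78 ± 0.071) and Kcnk4 (-0.63 ± 0.082), Fgf11 (-0.72 ± 0.12), Pld5 (-0.71 ± 0.10), the integrin Itga8 (-0.67 ± 0.076), the decoy receptor Tnfrsf11b (-0.64 ± 0.11) and Begain (-0.60 ± 0.062). The cadherin Cdh7 (-0.74 ± 0.16), the hormone gene Stc1 (-0.65 ± 0.12), Hs3st5 (-0.61 ± 0.11) and the integrin Itgb6 (-0.59 ± 0.13) were lower too. For these 24 genes all 6 lesioned arrays lay on one side of all 3 intact arrays, with adjusted p of 2.1e-05 to 0.023. Nr4a2 (2.11 ± 0.29), Fosb (1.45 ± 0.21), Trh (1.56 ± 0.28) and the enkephalin precursor Penk (0.29 ± 0.066) rose too, at adjusted p of 6.5e-04 to 0.024. The first 3 of these were high in the dyskinetic arrays: the dyskinetic, non-dyskinetic and intact means were 10.56, 7.11 and 6.72 for Nr4a2, 9.71, 7.75 and 7.28 for Fosb and 10.94, 7.86 and 7.84 for Trh, against 12.70, 12.62 and 12.38 for Penk. Pdyn (0.54, adjusted p = 0.059), Th (0.46, adjusted p = 0.10), Drd1 (-0.21, adjusted p = 0.15) and Drd2 (adjusted p = 0.48) did not pass.

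Of 17 immediate early genes 14 rose and none fell (16 adjusted over the list alone; camera adjusted p = 1.5e-18, adjusted p = 0.092 with an estimated correlation). The mean of that list was 10.04 ± 0.22 (SD, n = 3) in dyskinetic, 8.91 ± 0.49 in non-dyskinetic and 8.61 ± 0.07 in intact rats, so most of the difference lay in the dyskinetic arrays. Of 12 neuropeptides and secreted factors 7 rose (8 up and 2 down adjusted over the list alone). The camera adjusted p of that list was 2.3e-09, and adjusted p = 0.086 with an estimated correlation. Of 9 direct-pathway markers the muscarinic receptor Chrm4 (-0.48 ± 0.10) and the transcription factor Isl1 (-0.30 ± 0.072) fell over all genes, and 6 fell and 1 rose adjusted over the list alone. The camera call (adjusted p = 0.0029) was lost with the estimated correlation (adjusted p = 0.086 with an estimated correlation). The mean of these markers was 9.68 ± 0.03 (SD, n = 3) in dyskinetic, 9.49 ± 0.03 in non-dyskinetic and 9.73 ± 0.04 in intact rats. Pdyn, 1 of the 9, was 1.66 higher in dyskinetic than non-dyskinetic rats and counts toward these means. They therefore do not place the fall of the markers in either lesioned group. No microglial marker passed over all genes, while 7 of 14 rose and 1 fell adjusted over the list alone, with Cd68 at 0.67 and Tmem119 at 0.40 (camera adjusted p = 9.6e-04, adjusted p = 0.51 with an estimated correlation). Htr1b (0.58 ± 0.070) rose and Htr1d (-0.57 ± 0.077) and Htr2c (-0.45 ± 0.10) fell among 9 serotonin receptors.

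For this striatal comparison 434 genes passed, 273 higher and 161 lower, and 2258 had an unadjusted p under 0.05. The count was 168 without intact array 3, 186 without intact array 2, 257 without intact array 1, 663 without non-dyskinetic array 2, 244 with the median over probe sets and 754 with array weights. Without an intact array the highest adjusted p was 0.11 for Chrm4 and 0.17 for Penk (array 2), 0.14 for Isl1 (array 1) and 0.092 for Htr2c (array 3). It was 0.13 for Cdh7, 0.11 for Itgb6 and 0.050 for Hs3st5 (array 3) and 0.054 for Stc1 (array 2), and with trended variances that of Trh was 0.053. Among the immediate early genes Arc, Dusp1 and Nr4a1 lost their calls in 12 of 18 alternative settings. Npas4 lost its call in 11, Jun in 9, Egr2 and Junb in 7 each, and the others called in at most 2.

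Lesioned vehicle rats were compared with intact levodopa rats, which differ in lesion and drug at once, so no difference belongs to either alone. In the striatum Htr2a was at 10.39 ± 0.16 (SD, n = 3) against 9.13 ± 0.10 and rose by 1.26 ± 0.11. Nts rose by 1.72 ± 0.22, Nmu by 1.76 ± 0.28, Fst by 1.35 ± 0.17, Mmp9 by 1.01 ± 0.093, Tac3 by 0.97 ± 0.12, the melanocortin receptor accessory protein Mrap2 by 0.95 ± 0.10, the potassium channel subunit Kcnab3 by 0.97 ± 0.15, Pkp2 by 0.90 ± 0.13 and Cntnap3 by 0.83 ± 0.085. Tac1 stood at 10.22 ± 0.07 against 11.06 ± 0.11 and fell (-0.84 ± 0.11), as did Itga8 (-0.71 ± 0.088), Kcng1 (-0.65 ± 0.082), Begain (-0.49 ± 0.072), Rgs20 (-0.53 ± 0.084) and Drd1 (-0.50 ± 0.086). Penk rose by 0.39 ± 0.076, Inhba by 1.09 ± 0.19 and the heat shock gene Hspb1 by 1.04 ± 0.21, and Pld5 (-0.67 ± 0.12), Ptprv (-0.56 ± 0.11), Cyp2s1 (-0.55 ± 0.095), the neurofilament Nefm (-0.55 ± 0.10), Dok5 (-0.55 ± 0.092) and Sntg2 (-0.54 ± 0.089) fell. The groups did not overlap for any of these 25 genes, with adjusted p of 9.2e-05 to 0.038. Pdyn (-0.77, adjusted p = 0.069), Nr4a2 (0.17, adjusted p = 0.97), Fosb (0.30, adjusted p = 0.87), Trh (-0.15, adjusted p = 0.97), Th (0.30, adjusted p = 0.75) and Drd2 (0.13, adjusted p = 0.68) did not pass.

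The 9 direct-pathway markers were lower as a group: 3 fell over all genes (Tac1, Drd1 and Slc35d3, -0.40 ± 0.069), 6 adjusted over the list alone, and none rose. Camera passed with both correlations (adjusted p = 3.4e-10, and adjusted p = 0.0024 with an estimated correlation). Of 5 indirect-pathway markers Penk rose (1 adjusted over the list alone), and the camera call of that list (adjusted p = 0.034) was lost with the estimated correlation (adjusted p = 0.35 with an estimated correlation). Microglial markers did not pass over all genes and 6 of 14 rose adjusted over the list alone, among them Tyrobp (0.71) and Cd68 (0.77). For the list, camera gave adjusted p = 3.2e-09, and adjusted p = 0.35 with an estimated correlation. In total 55 genes passed, 33 higher and 22 lower, 968 had an unadjusted p under 0.05, and groups did not overlap in 14.8% of genes (10% by chance). The count was 25 without vehicle array 2, 26, 33 and 35 without intact arrays 3, 2 and 1, 35 with the median over probe sets and 191 with array weights. Highest adjusted p with an array left out was 0.099 for Drd1 and 0.064 for Nmu (vehicle array 2), 0.22 for Penk (intact array 2), and 0.065 for Rgs20 and 0.11 for Slc35d3 (intact array 3). Without intact array 3 it was also 0.24 for Hspb1, 0.18 for Nefm, 0.11 for Pld5, 0.10 for Inhba and 0.095 for each of Cyp2s1, Dok5 and Sntg2, and without intact array 2 it was 0.19 for Ptprv.

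In the nigra the lesion was seen in the transcripts of the dopamine neurons themselves. Th stood at 13.42 ± 0.06 (SD, n = 3) in intact rats, 10.80 ± 0.55 in vehicle, 11.46 ± 0.69 in dyskinetic and 12.27 ± 0.24 in non-dyskinetic rats. Set against intact rats on levodopa, the mean of both levodopa-treated lesioned groups was lower for Th (-1.56 ± 0.26), the dopamine transporter Slc6a3 (-1.92 ± 0.31), the vesicular monoamine transporter Slc18a2 (-2.40 ± 0.27) and the decarboxylase Ddc (-1.76 ± 0.19). The nicotinic receptor subunits Chrnb3 (-2.79 ± 0.27), Chrna6 (-2.50 ± 0.26) and Chrna5 (-2.11 ± 0.21), the receptors Tacr3 (-2.26 ± 0.20), Ntsr1 (-2.24 ± 0.21), Chrm5 (-2.12 ± 0.16) and Drd2 (-1.59 ± 0.15), and Slc10a4 (-2.30 ± 0.25), Cpne7 (-2.03 ± 0.23), Cadps2 (-2.00 ± 0.13), Dlk1 (-1.95 ± 0.21) and Nr4a2 (-1.94 ± 0.18) fell with them. Adjusted p of these 16 genes was 3.9e-06 to 0.0019, and each was lower in all 6 lesioned than in all 3 intact arrays. All 18 dopamine neuron markers fell, over all genes and adjusted over the list alone (median -1.56). As a list they had a camera adjusted p of 7.3e-24 (adjusted p = 0.072 with an estimated correlation).

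Among the largest rises of the same nigral comparison were the antigen-presentation genes Cd74 (1.99 ± 0.24), RT1-Da (1.69 ± 0.36) and RT1-Ba (1.07 ± 0.29), the complement component C3 (1.16 ± 0.13) and the iron-binding Lcn2 (0.93 ± 0.19). Ecel1, an endopeptidase induced in damaged neurons, rose by 1.27 ± 0.16, the immediate early gene Fos by 0.95 ± 0.14, the peptide precursors Pnoc by 0.94 ± 0.16 and Vgf by 0.88 ± 0.17, Timp1 by 0.85 ± 0.25, the interferon-induced protease Usp18 by 0.85 ± 0.16 and Fxyd5 by 0.77 ± 0.13. Of 14 microglial markers 7 rose and none fell (10 adjusted over the list alone), with Tyrobp at 0.76 ± 0.14 and Cd68 at 0.58 ± 0.10 (camera adjusted p = 8.3e-08, adjusted p = 0.36 with an estimated correlation). Of 12 oligodendrocyte markers 5 rose (9 adjusted over the list alone), such as Olig1 (0.38 ± 0.071). With camera the list was at adjusted p = 7.9e-06, and at adjusted p = 0.36 with an estimated correlation. Of 18 immediate early genes 9 rose, among them Egr1 (0.85 ± 0.19) and Arc (0.60 ± 0.081), and Nr4a2 fell (11 up and 1 down adjusted over the list alone). The camera adjusted p of the list was 9.1e-07, and adjusted p = 0.072 with an estimated correlation. Its mean was 8.19 ± 0.06 (SD, n = 3) in dyskinetic, 7.76 ± 0.08 in non-dyskinetic and 7.69 ± 0.06 in intact rats, so here too most of the difference lay in the dyskinetic arrays. Gabra4 (-0.99 ± 0.093) and Gabbr2 (-0.36 ± 0.070) fell and Gabra2 (0.29 ± 0.052) rose among 14 GABA genes, and Htr3a (-0.61 ± 0.054) fell among 10 serotonin receptors. Gabra3, Gabrg1, Htr2a and Htr4 of these lists also passed over all genes. Fosb rose by 0.36 ± 0.10, and Drd1 (adjusted p = 0.97), Trh (adjusted p = 0.87), Pdyn (-0.15, adjusted p = 0.41) and Penk (0.32, adjusted p = 0.55) did not pass.

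That comparison called 1558 nigral genes, 504 higher and 1054 lower, of 3349 with an unadjusted p under 0.05; 69 of the 74 that changed by at least a doubling were lower in the lesioned rats. The split between higher and lower depended on the scaling: values quantile-normalized again gave 737 higher and 900 lower. The count was 632 without intact array 2, 1008 without intact array 1 and 2570 with array weights. RT1-Ba, Timp1 and Fosb lost their calls when single arrays were left out, with highest adjusted p of 0.14 (intact array 1), 0.15 (intact array 2) and 0.13 (intact array 3).

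**Figure D3:**
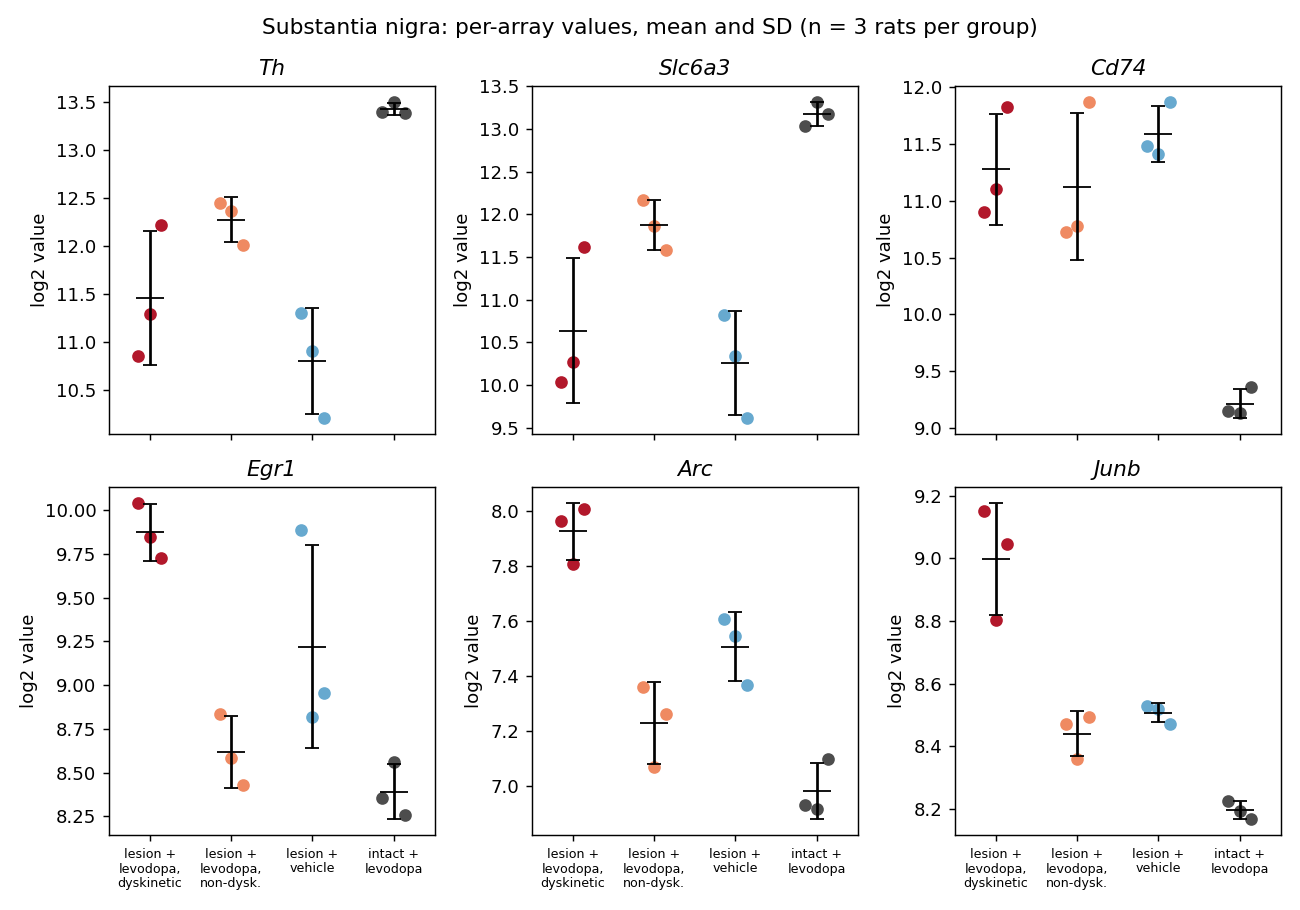
Each point is the log2 value of a gene on a nigral array, with the mean and SD of the 3 arrays per group, for Th, Slc6a3, Cd74, Egr1, Arc and Junb. Th and Slc6a3 are highest and Cd74 lowest in the intact rats, and Arc and Junb are highest in the dyskinetic rats.

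The nigra of lesioned vehicle rats was lower than that of intact levodopa rats in the same dopamine neuron genes. Chrnb3 (-3.79 ± 0.31), Chrna6 (-3.69 ± 0.30), Slc18a2 (-3.31 ± 0.31), Slc10a4 (-3.22 ± 0.29), Ntsr1 (-3.00 ± 0.24), Slc6a3 (-2.92 ± 0.36), Dlk1 (-2.78 ± 0.24), Ddc (-2.68 ± 0.22), the retinaldehyde dehydrogenase Aldh1a1 (-2.68 ± 0.17), Th (-2.62 ± 0.30), Chrm5 (-2.57 ± 0.19) and Chrna5 (-2.50 ± 0.25) fell. Nr4a2 (-2.47 ± 0.21) and Drd2 (-1.67 ± 0.17) were lower as well. Cd74 was at 11.59 ± 0.25 against 9.21 ± 0.13 (SD, n = 3) and rose by 2.38 ± 0.28, with RT1-Da (2.06 ± 0.42), RT1-Ba (1.56 ± 0.34), Ecel1 (adjusted p = 4.9e-04), the complement inhibitor Serping1 (1.30 ± 0.20), RT1-S3 (1.21 ± 0.23), the metallothionein Mt1 (1.14 ± 0.16), Mfrp (1.52 ± 0.18), the matrix protein Prelp (1.12 ± 0.22) and the immediate early gene Npas4 (1.07 ± 0.23). Hspb1 (1.36 ± 0.36) and Timp1 (1.09 ± 0.29) rose too, but were at adjusted p of 0.12 and 0.096 without intact array 2. The groups did not overlap for these 26 genes (adjusted p 4.8e-06 to 0.028). Fosb, Pdyn, Trh, Penk and Drd1 did not pass (adjusted p = 0.45, 0.59, 0.36, 0.23 and 0.42, with log2 differences of 0.14, 0.11, 0.14, 0.67 and 0.40).

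All 18 dopamine neuron markers fell in vehicle against intact rats, over all genes and adjusted over the list alone (median -2.44). The camera adjusted p of that list was 8.1e-28, and adjusted p = 0.095 with an estimated correlation. Of 14 microglial markers 3 rose (11 adjusted over the list alone; camera adjusted p = 2.2e-05, adjusted p = 0.53 with an estimated correlation). Of 18 immediate early genes 8 rose and 1 fell (10 and 1 adjusted over the list alone). Over the list camera gave adjusted p = 9.4e-04, and adjusted p = 0.27 with an estimated correlation. Of 9 interferon genes 3 rose and 1 fell (5 and 1 adjusted over the list alone), with Usp18 at 1.00 ± 0.18 (camera adjusted p = 0.013, adjusted p = 0.53 with an estimated correlation). Cck fell (-1.63 ± 0.16) and Npy, the neuropeptide Y precursor, rose (1.02 ± 0.21). Of 12436 genes 1589 passed, 686 higher and 903 lower, 3587 had an unadjusted p under 0.05, and groups did not overlap in 32.7% of genes (10% by chance). Values quantile-normalized again gave 844 higher and 880 lower. The count was 631 without intact array 2, 1049 without vehicle array 1, 941 with the median over probe sets, 973 with only these arrays in the fit and 3725 with array weights. Markers of other tissue were high in some vehicle arrays of the nigra: the mean of the pan-projection neuron markers was 9.88 in vehicle array 1 and 8.92 to 9.11 in the other nigral arrays, and Slc17a7, a marker of cortical glutamatergic neurons, was at 9.76 in vehicle array 3 and at most 6.87 in the others. In that array the mean of 14 markers of the leptomeninges, listed after seeing the data, was 9.48, against 8.38 to 8.76 in the other nigral arrays. Without vehicle arrays 1 and 3, a comparison chosen after seeing the data, 542 genes passed, 113 higher and 429 lower, and 44 of 84 named calls held. That leaves 1 vehicle array, assumed to vary like the other groups, so a lost call can come from fewer arrays alone. RT1-Da (1.99 ± 0.59, adjusted p = 0.088), Serping1 (1.00 ± 0.27, 0.062), Usp18 (0.92 ± 0.27, 0.082), Npas4 (1.19 ± 0.33, 0.072), Hspb1 (1.26 ± 0.34, 0.064) and Timp1 (0.64 ± 0.25, 0.20) were among the calls lost there.

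Dyskinetic and non-dyskinetic rats differed in fewer nigral genes, again with immediate early genes higher. Egr1 was at 9.87 ± 0.16 (SD, n = 3) against 8.62 ± 0.21 and rose by 1.26 ± 0.22, Arc by 0.70 ± 0.093 and Junb by 0.56 ± 0.081. The potassium channel subunit Kcne5 (1.01 ± 0.13), Grifin (0.90 ± 0.16), the adhesion receptor PVR (0.83 ± 0.10), the tubulins Tubb6 (0.82 ± 0.12) and Tubb2b (0.75 ± 0.11) and Dio2, which activates thyroid hormone (0.78 ± 0.11), rose. Bcl6b (0.70 ± 0.10), Tmem88 (0.67 ± 0.11), Hsd11b1, which activates glucocorticoids (0.60 ± 0.078), and Adgrl4 (0.58 ± 0.082) were also higher. Ret, the receptor subunit for GDNF, fell (-0.62 ± 0.089), as did Ngdn (-0.70 ± 0.12), Dnah12 (-0.66 ± 0.11), Acsm5 (-0.62 ± 0.088), Nxpe1 (-0.47 ± 0.065), the kinase Wnk2 (-0.46 ± 0.073), the acetyl-CoA carboxylase Acacb (-0.43 ± 0.071), D430041D05Rikl (-0.38 ± 0.061) and the AMP deaminase Ampd3 (-0.36 ± 0.064). The adjusted p of these 22 genes was 0.010 to 0.037, and the groups did not overlap for any. Fosb (0.53, adjusted p = 0.099), Nr4a2 (-0.23, adjusted p = 0.66), Drd1 (-0.10, adjusted p = 0.91), Drd2 (-0.54, adjusted p = 0.19), Slc18a2 (-0.87, adjusted p = 0.23), Ddc (-0.51, adjusted p = 0.31), Penk (0.63, adjusted p = 0.43), Pdyn (adjusted p = 0.93) and Trh (adjusted p = 0.91) did not pass.

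The 18 immediate early genes were higher as a group in the dyskinetic nigra: 3 rose over all genes and 11 adjusted over the list alone, with Dusp1 at 0.83 and Fos at 0.80, and none fell. The list passed camera with both correlations (adjusted p = 1.5e-12, and adjusted p = 0.014 with an estimated correlation). Of 18 dopamine neuron markers Ret alone fell over all genes and 8 adjusted over the list alone, among them Chrnb3 (-1.45), Chrna6 (-1.31) and Slc6a3 (-1.24, adjusted p = 0.17 over all genes). That list had a median of -0.47 (camera adjusted p = 1.9e-06, adjusted p = 0.46 with an estimated correlation), and Th was at -0.82 (adjusted p = 0.24). Of 14 ERK feedback genes Etv4 rose (0.45 ± 0.064; 3 adjusted over the list alone). For the list, camera gave adjusted p = 1.8e-04, and adjusted p = 0.14 with an estimated correlation. With limma 30 genes passed, 21 higher and 9 lower, 1813 had an unadjusted p under 0.05, and groups did not overlap in 21.3% of genes (10% by chance). Without dyskinetic array 1 the count was 0 by limma, with 1326 genes at an unadjusted p under 0.05, so every call of this comparison was lost; Kcne5, PVR and Hsd11b1 were then at an adjusted p of 0.051 and Egr1 at 0.17. It was 16 and 12 without dyskinetic arrays 2 and 3 and 9 and 11 without non-dyskinetic arrays 1 and 2. It was 17 with the lower 50% of genes left out, 16 with the median over probe sets, 104 with array weights, 54 with all 24 arrays in the fit and 55 without vehicle arrays 1 and 3.

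Against lesioned vehicle rats, the dyskinetic nigra was higher in Kcne5 (1.70 ± 0.13), Grifin (1.17 ± 0.16), the carboxypeptidase inhibitor Lxn (1.15 ± 0.12) and the amino acid transporter Slc7a10 (1.15 ± 0.10). Dio2 (0.88 ± 0.11), Bcl6b (0.85 ± 0.10), Tubb6 (0.85 ± 0.12), Hsd11b1 (0.82 ± 0.078), PVR (0.82 ± 0.10) and Tubb2b (0.78 ± 0.11) rose too, as did Aldh1a1 (0.93 ± 0.17) and Lcn2 (1.09 ± 0.22). The largest falls were those of Mfrp (-1.64 ± 0.18), Aebp1 (-1.15 ± 0.23), Dnah12 (-1.08 ± 0.11), Acsm5 (-1.08 ± 0.088), Fndc7 (-1.05 ± 0.20), the cystine transporter Slc7a11 (-1.02 ± 0.16), the bombesin receptor Grpr (adjusted p = 0.016), Synpo2 (-0.96 ± 0.22), the growth-factor binder Igfbp5 (-0.96 ± 0.12), the protease inhibitor A2m (-0.93 ± 0.17), Celsr1 (-0.91 ± 0.16) and Cidea (-0.88 ± 0.17). The groups did not overlap for these 24 genes (adjusted p 1.1e-04 to 0.047). Of 18 immediate early genes Junb (0.49 ± 0.081), Fosb (0.48 ± 0.11) and Arc (0.42 ± 0.093) rose and none fell (8 adjusted over the list alone). As a list they had a camera adjusted p of 2.2e-05 (adjusted p = 0.17 with an estimated correlation). The glutamate receptor subunits Grin2b (-0.70 ± 0.15) and Grin2a (-0.44 ± 0.075) fell of 16 glutamate receptor genes (camera adjusted p = 0.056). Among 18 dopamine neuron markers Aldh1a1 rose and Ret (-0.45 ± 0.089) fell, with a list median of 0.33 (camera adjusted p = 0.0014, adjusted p = 0.52 with an estimated correlation). Th (0.65, adjusted p = 0.24), Slc6a3 (0.38, adjusted p = 0.56), Slc18a2 (0.47, adjusted p = 0.40), Ddc (0.66, adjusted p = 0.12), Nr4a2 (0.42, adjusted p = 0.26), Pdyn (-0.28, adjusted p = 0.22), Drd1 (-0.42, adjusted p = 0.44), Drd2 (-0.18, adjusted p = 0.55), Penk (adjusted p = 0.96) and Trh (-0.10, adjusted p = 0.58) did not pass.

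The markers of other tissue in vehicle arrays 1 and 3 of the nigra bear on this comparison as well: pan-projection neuron markers had a median of -0.38, with none of 12 past over all genes and 2 lower adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.52 with an estimated correlation). In total 276 genes passed, 95 higher and 181 lower, with 2605 at an unadjusted p under 0.05 and groups that did not overlap in 25.7% of genes (10% by chance). Values quantile-normalized again gave 110 higher and 123 lower. The count ran from 34 without dyskinetic array 3 to 986 without vehicle array 2, and was 57 and 83 without dyskinetic arrays 1 and 2 and 54 and 105 without vehicle arrays 1 and 3. Without both vehicle arrays 1 and 3, chosen after seeing the data, 19 genes passed, 12 higher and 7 lower, 13 of them among the 276. Other settings gave 174 with no filter, 87 with the median over probe sets, 36 with only these arrays in the fit, 3393 with array weights and 457 with all 24 arrays. Of the 33 named calls 15 held whichever single array was left out. Of these 15, 8 held without both vehicle arrays 1 and 3 as well (Kcne5, Lxn, Slc7a10, Tubb6, Hsd11b1, Mfrp, Dnah12 and Acsm5), and 7 did not, at adjusted p of 0.057 to 0.11. These were Grifin (0.74 ± 0.15 there), Dio2 (0.75 ± 0.15), Bcl6b (0.81 ± 0.14), PVR (0.69 ± 0.13), Tubb2b (0.64 ± 0.12), Etv4 (0.48 ± 0.088, from 0.58 ± 0.064) and Igfbp5 (-0.70 ± 0.14). Of the 33, 9 held there, the ninth being Grpr, and Aebp1 was at -0.77 ± 0.19 (adjusted p = 0.21). The 1 vehicle array left was assumed to vary like the other groups, so lost calls can come from fewer arrays alone. Highest adjusted p without dyskinetic array 3 was 0.17 for Arc, 0.17 for Fosb, 0.13 for Grin2b, 0.15 for Synpo2, 0.090 for Fndc7, 0.090 for Cidea, 0.079 for A2m, 0.078 for Grpr, 0.078 for Junb, 0.075 for Celsr1 and 0.054 for Slc7a11. Without dyskinetic array 1 it was 0.11 for Ret and 0.091 for Aebp1, and without vehicle array 1 it was 0.085 for Lcn2, 0.078 for Aldh1a1 and 0.060 for Grin2a.

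Genes called against both other lesioned groups in the nigra numbered 18 higher and 8 lower in dyskinetic rats, where independence gives 0.160 and 0.131. That value leaves out the shared dyskinetic arrays, and simulated data without an effect, with an overlap of 0 in 50 simulations, call almost no gene, so neither bounds the overlap. The fold changes correlated across genes at r = 0.668 with a covariance of 0.0180, against 0.505 and 0.00623 in the simulations, and part of this excess may likewise come from the shared dyskinetic arrays.

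No nigral gene passed between non-dyskinetic and lesioned vehicle rats by limma, and 999 had an unadjusted p under 0.05. The most extreme statistics were, on the higher side, those of Slc7a10 (0.76, adjusted p = 0.074), Fgf1 (0.81), Chrna6 (1.84), Chrnb3 (1.73) and Cck (0.87), and on the lower side those of Tnfsf13 (-0.52, adjusted p = 0.074), Ptgs2 (-0.62), Gabra2 (-0.34), Cacng5 (-0.62) and Fam107a (-0.71), at adjusted p of 0.074 to 0.12. Of 18 dopamine neuron markers none passed over all genes and 14 were higher in non-dyskinetic rats adjusted over the list alone, with Slc6a3 at 1.62 (adjusted p = 0.23 over all genes), Slc18a2 at an adjusted p of 0.27 over all genes, Ddc at 1.17 (adjusted p = 0.12) and Th at 1.47 (adjusted p = 0.17 over all genes). The median of the list was 0.79 (camera adjusted p = 7.7e-23, adjusted p = 0.16 with an estimated correlation). Immediate early genes had a median of -0.11 with none past either way (camera adjusted p = 0.011, adjusted p = 0.33 with an estimated correlation). Pan-projection markers, which were high in vehicle array 1, had a median of -0.29 (camera adjusted p = 4.7e-04, adjusted p = 0.62 with an estimated correlation). Fosb, Pdyn, Nr4a2, Trh, Penk, Drd1 and Drd2 did not pass (adjusted p = 0.94, 0.65, 0.51, 0.77, 0.67, 0.82 and 0.62). The count was 37 without vehicle array 2, 6 without vehicle array 1, 67 with array weights, 26 with all 24 arrays in the fit and at most 3 otherwise. Groups did not overlap in 10.9% of genes (10% by chance).

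Whether the dyskinesia difference itself was unlike in striatum and nigra was tested gene by gene over all 24 arrays. The difference was larger in the striatum for Nr4a2 (by 3.62 ± 0.41), Trh (3.03 ± 0.36), Nmu (2.25 ± 0.32), Cdkn1a (2.11 ± 0.30), Cck (2.07 ± 0.24), Inhba (2.03 ± 0.23), Sstr2 (2.02 ± 0.18), Gpr3 (1.95 ± 0.27), Dusp2 (1.88 ± 0.19), Pdyn (1.69 ± 0.22) and Fosb (1.42 ± 0.28). It was larger for Th by 1.91 ± 0.36, where the striatal difference was 1.15 and the nigral one -0.82. It was smaller or more negative in the striatum for Syt2 (-0.95 ± 0.17), the receptor kinase Ltk (-0.56 ± 0.10), Nexn (-0.63 ± 0.13), Trib2 (-0.62 ± 0.13) and Grifin (-0.79 ± 0.18). The same held for Gpr139 (adjusted p = 0.040), Sytl5 (-0.68 ± 0.17), Entpd3 (-0.57 ± 0.14), Tmem44 (-0.57 ± 0.14), Iqgap3 (-0.57 ± 0.13), Plxnd1 (-0.56 ± 0.13) and the transporter Slc22a3 (-0.56 ± 0.14), and Timp1 had the larger striatal difference (2.14 ± 0.54). Adjusted p of these 25 genes was 1.3e-06 to 0.048. Drd1 (0.24, adjusted p = 0.87), Drd2 (0.43, adjusted p = 0.34) and Penk (-0.57, adjusted p = 0.63) did not pass.

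Neuropeptides and secreted factors differed between the tissues as a group: 5 of 14 had the larger striatal difference (6 adjusted over the list alone), and camera passed with both correlations (adjusted p = 4.7e-08, and adjusted p = 0.014 with an estimated correlation). For the tissue difference camera took no animal block and treated the arrays as independent. Its p values for the lists therefore leave out that most animals gave both tissues. Of 18 immediate early genes 4 had a larger striatal difference (8 larger and 1 smaller adjusted over the list alone). With camera the list was at adjusted p = 1.6e-10, and at adjusted p = 0.12 with an estimated correlation. Of 17 dopamine neuron markers Th, Chrnb3 (1.41 ± 0.33) and Chrna6 (1.31 ± 0.31) differed (9 adjusted over the list alone; camera adjusted p = 1.5e-10, adjusted p = 0.11 with an estimated correlation). Of 14 ERK feedback genes 5 were larger and 1 smaller in the striatum. That list had a median of -0.066 against a mean of 0.30 and a camera direction of up (adjusted p = 0.14). Arc, Junb, Bcl6b, Dio2, Kcne5, PVR, Tubb6, Tubb2b, Cflar, Adgrl4, Tmem88 and Hsd11b1 were higher and D430041D05Rikl and Nxpe1 lower in dyskinetic than non-dyskinetic rats in both tissues, 14 genes in all. Independence gives 0.634 higher and 0.131 lower in both, but leaves out that 5 rats gave arrays to both comparisons, and without nigral dyskinetic array 1 limma left no nigral call to overlap (1326 genes at an unadjusted p under 0.05). The difference between tissues passed for none of them, the lowest adjusted p being 0.086 for PVR. The test called 190 genes, 163 with the larger and 27 with the smaller difference in the striatum, and 1399 had an unadjusted p under 0.05. The count was 95 without striatal dyskinetic array 2, 320 without striatal dyskinetic array 3, 111 without nigral dyskinetic array 2 and 124 with the median over probe sets. Of the genes named, Chrnb3 and Chrna6 (adjusted p 0.12 and 0.12) and Grifin (0.13) were lost without nigral dyskinetic array 2, and Nexn (0.079), Sytl5 (0.22), Timp1 (0.17), Slc22a3 (0.16), Entpd3 (0.15) and Plxnd1 (0.11) without striatal dyskinetic array 2. Without striatal non-dyskinetic array 2 Trib2 (0.064), Gpr139 (0.13) and Tmem44 (0.15) were lost, and Iqgap3 (0.11) without nigral non-dyskinetic array 2. These were not the only losses. Over 21 alternative settings Gpr139 and Timp1 lost the call in 14, and Chrna6, Sytl5 and Tmem44 in 12 each. Entpd3 and Slc22a3 lost it in 11 each, Chrnb3 in 10, Iqgap3 in 9, Grifin and Plxnd1 in 6 each, Trib2 in 5 and Nexn in 3.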

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

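The tests of dopamine neuron loss per array, of cortical and meningeal tissue in vehicle array 3 and of poor hybridisation were chosen only after the result was seen, as was the comparison without vehicle arrays 1 and 3 of the nigra.

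The dyskinesia difference was unlike in striatum and nigra for 190 genes by a direct test of the difference. The striatal difference exceeded the nigral one by 1.42 for Fosb, 1.69 for Pdyn, 3.62 for Nr4a2, 3.03 for Trh and 1.91 for Th. Probe sets outside the genes analysed also carried signal between dyskinetic and non-dyskinetic rats: of 28861 that name no gene 38 passed in striatum (31 higher, 7 lower; 2600 at an unadjusted p under 0.05) and 2 in nigra (1 higher, 1 lower; 2884 unadjusted). Of 1245 that name several genes 2 passed in striatum (both higher; 124 unadjusted) and 0 in nigra by limma (129 unadjusted).

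The list of 18 dopamine neuron markers had a median of -0.47 between dyskinetic and non-dyskinetic nigra, but only Ret passed over all genes and the list was at adjusted p = 0.46 with an estimated correlation. Less midbrain tissue in the dyskinetic punches was tested as the whole cause. As a set, 66 other genes enriched in nigra over striatum had a median difference of -0.081 (quartiles -0.20 and 0.052) against -0.47. Genes called lower in levodopa-treated lesioned or vehicle rats than in intact rats had been left out of this set. The first of those comparisons holds the dyskinetic arrays, so genes low in them could be dropped beforehand. The small median therefore does not decide against less midbrain tissue. A more complete loss of dopamine neurons in the dyskinetic rats may lie behind the lower dopamine list. The mean of the list per array was 8.71 ± 0.39 in dyskinetic, 9.25 ± 0.17 in non-dyskinetic and 8.38 ± 0.19 in vehicle rats (SD, n = 3). The dyskinetic and non-dyskinetic arrays overlapped. The first of these differences was -0.54 (exact permutation test, two-sided, p = 0.2, where 0.1 is the smallest possible). It stays open, since the design gives no lesion size per animal, and lower expression per neuron was not tested. The 66 genes were picked against striatum alone, so they cannot tell whether a punch was placed elsewhere in the midbrain. The mean of the midbrain glutamatergic markers was 7.60 ± 0.31 in dyskinetic and 7.15 ± 0.49 in non-dyskinetic nigra (SD, n = 3), with overlapping arrays. Punch placement stays open too.

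Vehicle arrays 1 and 3 of the nigra stood apart from the other nigral arrays. Of the 100 genes with the largest excess in striatum 66% were highest in vehicle array 1, against 23% for the next array and 8.33% by chance, and Rgs9 was at 9.66 there and at most 7.95 elsewhere, so striatal tissue may be part of that punch. In vehicle array 3 Slc17a7, Itgbl1, C1ql3, the blood gene Alas2, Slc13a4, Gda, Ranbp3l, Htra4, Nrp2 and Bmp6 stood over 1.7 above all other arrays. Meningeal tissue may be part of that punch. Of 14 leptomeningeal markers, which the nigra also expresses, 85.7% were highest there against 7.14% in the next array. Among them were Ptgds (12.94, at most 12.31 elsewhere), Ogn (11.35, at most 10.38) and Dcn (10.59, at most 10.00). Cortical tissue stays open. Of 4 cortical markers only Slc17a7 was highest there, but it stood further above the other arrays than any other gene (by 2.89). Poor hybridisation was argued against, since 4 genes lay below and 142 above all other arrays by over 0.5, a ratio of 0.028. No biological explanation was tested, because the labels set these rats in no group of their own.

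Immediate early genes were higher in the dyskinetic nigra. Striatal tissue in those punches could bring such transcripts, but the 12 pan-projection neuron markers had a median difference of -0.088 (SD over markers 0.12), and even the smallest share of striatal tissue that would bring the rise, 2.86%, needs 0.18. The mean of these markers per array was 8.92 to 8.97 in dyskinetic and 9.00 to 9.04 in non-dyskinetic nigra. These values argue against striatal tissue as the whole source of the rise. They do not exclude it, since the share was estimated across tissues with different array medians and the SD is over markers, not rats. A difference in the activity of nigral cells between the groups stays open as untested.

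Other splits of the compared arrays into groups of the same sizes were counted for each comparison. Groups of 3 against 3 make 10 splits, too few for a share under 0.05. In striatum dyskinetic against non-dyskinetic rats gave 654 genes and the highest other split 0, dyskinetic against vehicle 644 and 0, and vehicle against intact 55 and 0, so 1 of 10 splits gave as many in each. Non-dyskinetic against vehicle gave 4 and another split 5, so 2 of 10 gave as many. In nigra the values were 30 and 0 for dyskinetic against non-dyskinetic, 276 and 0 for dyskinetic against vehicle and 1589 and 0 for vehicle against intact (1 of 10 each), and 0 and 1 for non-dyskinetic against vehicle, where all 10 gave as many. The tissue difference gave 190 genes and 0 in the other splits of 6 units (1 of 10), where each unit is an animal, except that 1 joins the striatum of a dyskinetic rat with the nigra of another. For the mean of both levodopa-treated lesioned groups against intact rats 84 splits were possible. In nigra 1 of 84 gave as many (1558, highest other 1273, with the dyskinetic arrays set apart), and in striatum 3 of 84 did. Splits that mix the groups raise the spread within groups, so splits that keep groups whole tend to call more genes. A share under 0.05 thus shows that the arrays fall into groups. It does not exclude chance for lesioned against intact rats. One of these 3 in striatum called 1416 genes against the real 434 and set the dyskinetic arrays apart, which points to a structure of the samples: the 6 lesioned arrays are not alike. Another, with intact arrays 2 and 3 and non-dyskinetic array 2 set apart, called 472.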

How the results depend on the processing

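Leaving out both vehicle arrays 1 and 3 of the nigra was chosen only after the result was seen. Signal over background was not analysed here; the number of arrays limits precision throughout. Where arrays were left out of a group, the remaining ones, for vehicle nigra a single array in the first case, were assumed to vary like the other groups.

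Counts moved by over 1.5 times in these cases, and the cause was not tested. With the median over probe sets 352 genes passed for dyskinetic against non-dyskinetic striatum, 381 for dyskinetic against vehicle, 1 for non-dyskinetic against vehicle, 244 for levodopa-treated lesioned against intact and 35 for vehicle against intact. In nigra that setting gave 16 for dyskinetic against non-dyskinetic, 87 for dyskinetic against vehicle and 941 for vehicle against intact, and 124 for the tissue difference. With only the compared groups in the fit the values were 388 and 1 in striatum for dyskinetic and for vehicle against non-dyskinetic, and 36 and 973 in nigra for dyskinetic against vehicle and vehicle against intact. Array weights gave 1152 (dyskinetic against vehicle), 754 (levodopa-treated lesioned against intact) and 191 (vehicle against intact) in striatum and, in nigra, 104 for dyskinetic against non-dyskinetic, 3393 and 67 for dyskinetic and non-dyskinetic against vehicle, and 2570 and 3725 for levodopa-treated lesioned and vehicle against intact. Leaving out the lower 50% of genes gave 2 (non-dyskinetic against vehicle) in striatum and 17 and 2 in nigra (dyskinetic and vehicle against non-dyskinetic); no filter gave 174 for dyskinetic against vehicle nigra. For non-dyskinetic against vehicle nigra trended variances gave 1 and quantile normalization 2. All 24 arrays in the fit gave 11 for non-dyskinetic against vehicle striatum and 54, 457 and 26 for the nigral contrasts among lesioned rats. Without vehicle arrays 1 and 3 of the nigra dyskinetic against vehicle gave 19, dyskinetic against non-dyskinetic 55, non-dyskinetic against vehicle 1 and vehicle against intact 542.

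Single arrays left out gave 293 to 945, 382 to 636, 1 to 12, 168 to 663 and 25 to 43 genes in striatum and 0 (1326 at an unadjusted p under 0.05 by limma, without dyskinetic array 1) to 24, 34 to 986, 0 (by limma, 1102 unadjusted) to 37, 632 to 1748 and 631 to 1739 in nigra, in the order dyskinetic against non-dyskinetic, dyskinetic against vehicle, non-dyskinetic against vehicle, levodopa-treated lesioned against intact and vehicle against intact, and 95 to 320 for the tissue difference. The striatal count of 945 was reached without non-dyskinetic array 1.

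The replicate number was tried as a block although pairing was not used: arrays of the same number correlated at a mean r of 0.064 in striatum and 0.030 in nigra over 18 pairs each, against -0.032 and -0.015 for other numbers. The block gave 9 genes for non-dyskinetic against vehicle striatum, 143 for dyskinetic against vehicle nigra and 694, 683, 576 and 78 for the other striatal comparisons.

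Of 472 named calls none turned direction in 7846 refits, and 1171 refits lost the threshold, 744 of them among 3501 with an array left out. Within a tissue the rule required groups without overlap for the largest rises and falls. For such genes leaving out an array cannot turn the direction. Differences that did not pass gained the threshold in 62 of 1163 refits and turned sign in 28. In nigra dyskinetic minus vehicle Penk was 0.0062 with quantile normalization and 0.55 without vehicle arrays 1 and 3, where Trh was 0.030; Pdyn was 0.032 in dyskinetic minus non-dyskinetic and -0.015 in vehicle minus intact nigra with the median over probe sets, and Drd2 -0.012 in levodopa-treated lesioned minus intact striatum; Drd2 was 0.012 in non-dyskinetic minus vehicle striatum with quantile normalization. With single arrays left out the ranges in nigra were -0.77 to 0.082 for Drd1 and -0.35 to 0.57 for Penk (dyskinetic minus vehicle), -0.41 to 0.051 for Nr4a2, -0.12 to 0.092 for Pdyn and -0.055 to 0.088 for Trh (dyskinetic minus non-dyskinetic), -0.025 to 0.090 for Drd1 and -0.039 to 0.093 for Trh (levodopa-treated lesioned minus intact), -0.11 to 0.75 for Drd1 (vehicle minus intact), and -0.67 to 0.19 for Drd1 and -0.14 to 0.0015 for Fosb (non-dyskinetic minus vehicle). In striatum, non-dyskinetic minus vehicle, they were -0.040 to 0.031 for Drd2, -0.17 to 0.44 for Fosb and -0.22 to 0.49 for Nr4a2. Of 242 list tests 65 passed with the preset and 5 with the estimated correlation.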

Other observations

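In the nigra of levodopa-treated lesioned against intact rats S100b (0.17 ± 0.049) was the only one of 11 astrocyte markers to pass (camera adjusted p = 0.012, adjusted p = 0.59 with an estimated correlation). Of 9 endothelial and mural cell markers 3 rose, the transporter Slco1a4 (0.37 ± 0.10), the angiopoietin receptor Tek (0.35 ± 0.087) and Esam (0.26 ± 0.064), with a camera adjusted p of 0.014 (adjusted p = 0.63 with an estimated correlation). S100b lost its call without intact array 2 (adjusted p 0.13), as did Slco1a4 (0.17), Tek (0.14) and Esam (0.13). Over 19 alternative settings S100b lost its call in 9, Slco1a4 in 6, Tek in 3 and Esam in 2. Calb2, calretinin, fell (-1.13 ± 0.18), and with Th made 2 falls among 7 striatal interneuron markers, whose median of 0.030 differed in sign from the mean of -0.20 (camera adjusted p = 0.94). Oxidative phosphorylation genes had a median of 0.072 with none of 21 past (camera adjusted p = 0.042, adjusted p = 0.85 with an estimated correlation).

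In the same comparison Enpp2 rose (0.32 ± 0.081, but adjusted p 0.14 without intact array 2) among 6 choroid plexus markers, of which Ttr was at -0.43 (adjusted p = 0.31). The list median was -0.037 while camera put the list up (adjusted p = 0.99). Cux2 fell (-0.22 ± 0.056, but adjusted p 0.13 without intact array 2) among 4 cortical neuron markers (camera adjusted p = 0.94), and none of 4 midbrain glutamatergic markers passed (camera adjusted p = 0.72). Between dyskinetic and non-dyskinetic nigra the midbrain list had a median of 0.28 (camera adjusted p = 0.031, adjusted p = 0.46 with an estimated correlation).

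The mean of the immediate early genes on each striatal array was 10.17, 10.17 and 9.79 in dyskinetic rats, 9.36, 8.38 and 8.98 in non-dyskinetic rats, 8.57 to 8.75 in vehicle rats and 8.56 to 8.70 in intact rats.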
